A study of Bos taurus with 4 samples.

How the data were processed

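Total RNA was taken with TRIzol from frozen longissimus muscle, the long muscle along the back, of cattle aged 2 years, per the labels' protocols. Libraries were sequenced on an Illumina HiSeq instrument as single-end reads of 50 bases, per the labels' protocols and the series text. The labels put 2 libraries in a control group and 2 in a group given nicotinic acid (niacin, a form of vitamin B3 and a precursor of NAD). The series title speaks of 4 cattle, as many as there are libraries, while its design text speaks of 6 control and 6 treated animals. The labels do not say which animals, or how many, each library holds. Dose, route and duration of the nicotinic acid are not given in the sources used here.

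Each library has its own table with 1 line per Ensembl cattle transcript identifier. Per the file headers, the deposited tables give the count of uniquely mapped reads, the transcript length, the percent of the transcript's bases covered by reads, and an RPKM value, the count divided by the transcript's length and by the library's total. The counts are whole numbers whose sum equals the total in each header, and the RPKM values that the authors deposited equal that quotient of the same line's count and length, and of the header's total, to within 0.00001 percent. A transcript without a read is not listed, and was taken as 0 reads here. The submitters' processing notes name Bowtie2 and the UMD 3.1 cattle assembly; the version, settings and counting rule are not given in the sources used here. Nothing states how reads shared by transcripts of one gene, by near-identical copies or by overlapping genes on either strand were assigned, so any single transcript's count may miss or include such reads.

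The tables pair no identifier with a gene name. None of the 17158 identifiers (0 matched) occurs in the reference table used here, which lists genes of another assembly (ARS-UCD2.0) without Ensembl identifiers. Gene names and coordinates are therefore not used. The 34 gene lists fixed before the data were examined, 26 for functions such as fibre type, NAD metabolism and fat metabolism and 8 for cell types, could not be matched to the tables and were not tested. The rule fixed at the same time for naming genes needed symbols, so it named none. The 4 transcripts printed with their identifiers are the 2 with the smallest p in each direction, chosen after the values were seen.

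The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts of all 4 libraries, with TMM normalization, group as the sole term and Benjamini-Hochberg adjustment over all transcripts tested, at 0.05. filterByExpr with its defaults (a minimum count of 10, and of 15 in total) kept 12025 transcripts. A standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. TMM factors were 0.948 and 0.927 for the control libraries and 0.959 and 1.19 for nicotinic acid replicates 1 and 2. Because the title and the design text differ on the number of animals, it is open whether each library is 1 animal or a pool, and p-values measure only the spread between these samples.

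Counts were simulated for the 12025 transcripts of this comparison with the fitted means, library sizes and trended dispersions. No library was given a wider spread than another, and each transcript had the spread of the trend alone. The recovery may therefore be higher than in the real counts. The 200 transcripts changed were drawn from those expected at 20 or more reads, so the recovery does not cover rarer ones. Of these, edgeR called 20 of 50 changed by 2-fold, 48 of 50 by 4-fold, 50 of 50 by 8-fold and 50 of 50 by 16-fold. Of its 178 calls, 10 were false, and it made 0 calls with no change simulated. The alternatives fixed before the data were examined were other scalings (edgeR's RLE size factors, library totals alone), no filter, a mean RPKM of at least 5, limma 3.58.1 with a trended variance on log2(RPKM + 1) or log2(RPKM + 0.1) for transcripts with an RPKM of at least 1 in 2 libraries, DESeq2 1.42.0, a robust spread, a test against a log2 fold change of 1, each library left out in turn, and the replicate number as a block. Shares of reads carry Wilson 95 percent intervals (scipy 1.17.1). These intervals, and the floor of 3 reads used for a transcript with none, cover counting error only, since the reads carry no molecular identifiers.

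The replicate numbers 1 and 2 occur in both groups. Same-numbered libraries did not deviate together from their group means (correlation across transcripts of -0.0041), and the labels do not say that a number marks a shared animal, batch or day.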

Results

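The transcriptome of cattle longissimus muscle was measured in 2 control libraries and 2 libraries from cattle given nicotinic acid. The libraries held 15.2M and 14.7M uniquely mapped reads for control replicates 1 and 2, and 15.7M and 14.6M for nicotinic acid replicates 1 and 2. At these depths 3 reads correspond to between 0.191 and 0.205 CPM (counts scaled to a total of 1M reads). Reads fell on 17158 transcripts in all, of which 13784 were listed in all 4 libraries and 9382 reached 1 RPKM in all 4. Transcript lengths ran from 85 to 103346 bases, with a median of 1839. The tables identify transcripts by Ensembl number alone, so the changes are described by transcript, abundance class and library rather than by gene name.

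A small number of transcripts held most of the reads. In the control libraries 41 and 40 transcripts made up 50 percent of the reads, and in nicotinic acid replicate 1 the number was again 41. In nicotinic acid replicate 2 it was 72. The 10 most abundant transcripts of each library took 26.2% of the reads in control replicate 1 (95% interval 26.2 to 26.3), 27.2% in control replicate 2 (27.2 to 27.2) and 25.9% in nicotinic acid replicate 1 (25.9 to 25.9). They took 20.9% in nicotinic acid replicate 2 (20.8 to 20.9). The most abundant transcript alone took 5.61% and 7.14% of the control reads and 5.56% and 4.88% of the nicotinic acid reads.

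The comparison of nicotinic acid with control asked which muscle transcripts differ in the treated cattle. Few were detected: 6 of 12025 transcripts passed the threshold, 5 higher and 1 lower with nicotinic acid (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). DESeq2 called 60 (50 higher, 10 lower) and edgeR without a filter on low values 92, all 6 among them, and limma on log2(RPKM + 1) called 3 of the 6. All 6 changed by more than 4-fold, and in each the values of the 2 nicotinic acid libraries lay close together and far from those of both controls. Of all tested transcripts 11336 (94.3%) were fitted within 2-fold and 689 at 2-fold or more, with a median size of change of 0.24 on the log2 scale.

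ENSBTAT00000006074, a transcript of 2298 bases, rose most clearly. It had 25 and 15 reads in the control libraries and 709 and 764 in the nicotinic acid libraries. Its level was 0.58 ± 0.19 RPKM in controls and 21.2 ± 2.2 RPKM with nicotinic acid (SD, n = 2 each). The TMM-scaled log2 fold change was 4.99 ± 0.29 (SE), or 31.9-fold, with an edgeR adjusted p of 0.0055. RPKM is scaled to library totals instead, and the summed reads scaled in that way rose 36.3-fold. ENSBTAT00000026725, of 9381 bases, rose from 1.94 ± 0.04 to 16.9 ± 3.9 RPKM (SD, n = 2 each), 8.67-fold in summed reads scaled to library totals. Its TMM-scaled log2 fold change was 2.92 ± 0.22 (SE), or 7.58-fold, with an edgeR adjusted p of 0.013. This call was lost with control replicate 2 left out (adjusted p = 0.096) and in limma on log2(RPKM + 1) and log2(RPKM + 0.1), at 0.096 and 0.065.

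The transcript that fell was ENSBTAT00000048100, of 1568 bases. It had 856 and 973 reads in the control libraries and 122 and 91 with nicotinic acid, or 39.1 ± 4.4 against 4.46 ± 0.70 RPKM (SD, n = 2 each). Its summed reads scaled to library totals were 8.71-fold lower. With TMM scaling it was 9.80-fold lower, a log2 fold change of -3.29 ± 0.28 (SE), with an edgeR adjusted p of 0.016. The next transcript in that direction, ENSBTAT00000001120 of 6109 bases, had 11.4 ± 0.1 RPKM in controls and 1.81 ± 0.47 RPKM with nicotinic acid (SD, n = 2 each). Its TMM-scaled log2 fold change of -2.81 ± 0.30 (SE) missed the threshold narrowly, at an edgeR adjusted p of 0.052.

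The other 3 transcripts past the threshold were all higher with nicotinic acid, each at an edgeR adjusted p of 0.016. A transcript of 2354 bases went from 0.298 ± 0.013 to 7.74 ± 1.53 RPKM. Another, of 957 bases, went from 0.877 ± 0.267 to 16.1 ± 0.2 RPKM (SD, n = 2 each). The last, of 4103 bases, had only 4 and 3 control reads against 103 and 156. The ratio of its summed reads, scaled to library totals, was 36.5, with a 95% counting interval of 17.5 to 91.7. The transcript of 957 bases passed in all 14 alternative analyses. That of 2354 bases was lost in limma on log2(RPKM + 1) and log2(RPKM + 0.1), at adjusted p of 0.087 and 0.059. That of 4103 bases was lost in both too, at 0.80 and 0.49, and with library totals alone, at 0.083. A mean RPKM of at least 5 left both of these out of the test.

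**Figure D1:**
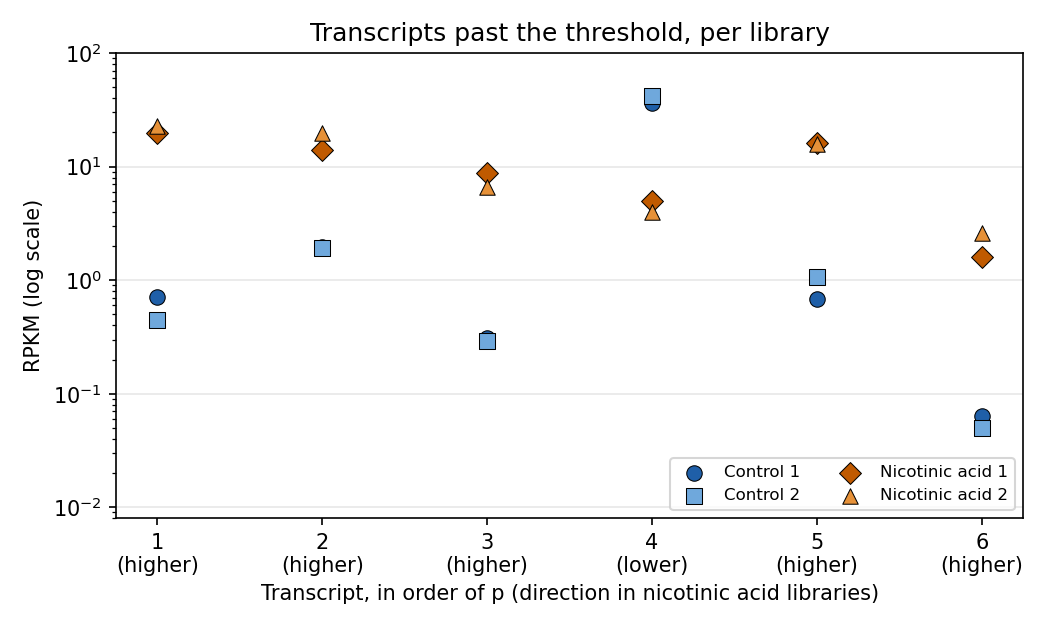
RPKM on a log scale for the 6 transcripts past the threshold, in order of p, with 1 point per library. In each of the 5 transcripts that were higher the 2 nicotinic acid libraries lie above both controls, and in transcript 4 (35.9 and 42.2 against 4.96 and 3.97 RPKM) they lie below.

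By abundance, 4 of the 6 transcripts had a mean between 1 and 10 RPKM and 2 a mean between 10 and 100 RPKM. None of the 514 transcripts with a mean over 100 RPKM passed, and 97.1% of these were fitted within 2-fold. At an unadjusted p under 0.05 there were 11 higher and 7 lower transcripts in that class. Among the 1745 transcripts with a mean under 1 RPKM, 0 passed by edgeR, with 86 higher and 32 lower at an unadjusted p under 0.05. Over all classes 746 transcripts had an unadjusted p under 0.05, 509 higher and 237 lower, or 6.20% of those tested. The other ways of dividing the 4 libraries into pairs gave 445 and 378 transcripts, and counts simulated with no change gave 4.26%. Neither is a baseline for the 746. The other splits count any group difference as spread within pairs, and the simulation gave each transcript the spread of the trend alone. The median log2 change fell from 0.096 under 1 RPKM to -0.131 over 100 RPKM. Nicotinic acid replicate 2 fell in the same way relative to the other 3 libraries (0.23 to -0.19 from the least to the most abundant 20% of transcripts). Nicotinic acid replicate 1 went from -0.056 to 0.047, and control replicates 1 and 2 from -0.024 to 0.055 and from -0.070 to 0.084. The mean that each of these was set against includes nicotinic acid replicate 2, whose fall alone turns their values upward. The direction of nicotinic acid replicate 1 is therefore no separate result. TMM placed the median change of all tested transcripts at 0.00 (log2), and library totals alone placed it at 0.20, so that the share fitted as higher was 50.5% with TMM and 71.8% with totals.

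**Figure D2:**
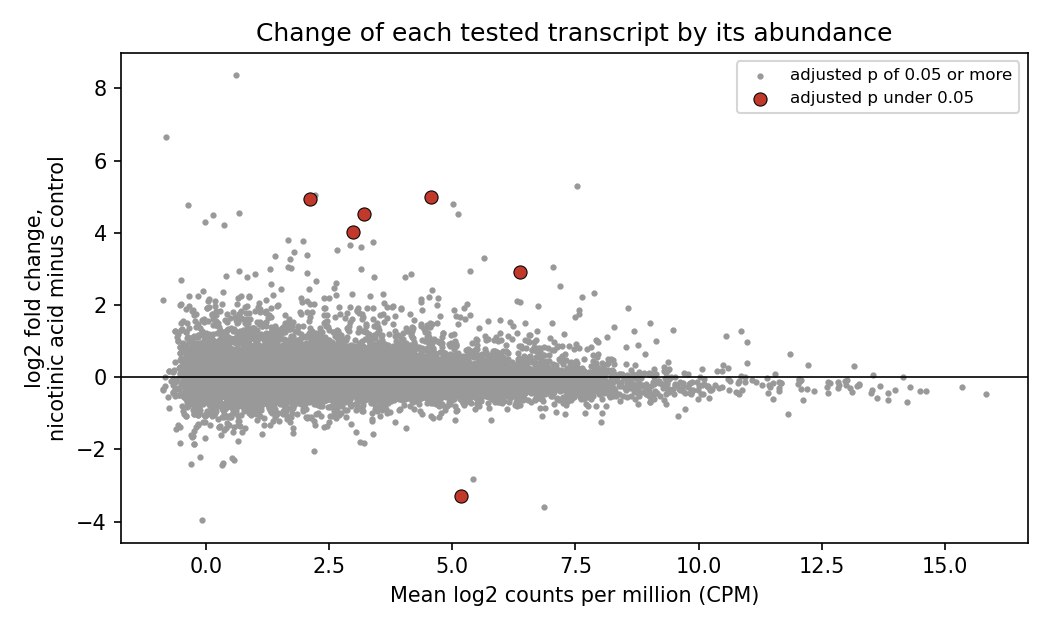
The log2 fold change of nicotinic acid minus control against mean log2 CPM, with 1 point per tested transcript. The 6 transcripts past the threshold lie at log2 changes between -3.29 and 4.99, while 94.3% of transcripts lie within 2-fold. In all, 101 were fitted at more than 4-fold, so size of change alone does not set the 6 apart. The highest points at the left have few or 0 control reads, and their fitted changes are not bounds.

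Large changes were of different kinds, which can share transcripts. A further 16 transcripts, of which 14 were tested and missed the threshold and 2 fell below the filter, had both nicotinic acid libraries at least 4-fold above or below both controls, with at least 1 RPKM in the higher group. Together with the 6 they made 22, of which 18 were higher and 4 lower. The other splits gave 2 and 8 such transcripts, but they mix the groups within pairs and are no baseline. Another kind rested on nicotinic acid replicate 2. The 101 tested transcripts fitted at more than 4-fold include the 6 past the threshold and were not kept separate from the 16. Of these 101, 90 were higher and 11 lower. In 41 of them nicotinic acid replicate 1 lay within 2-fold of the mean of the controls, in 0 nicotinic acid replicate 2 did, and in 60 both lay farther away. The values of the groups overlapped in 27 of the 101.

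Nicotinic acid replicate 2 stood apart from the other libraries. It had 232 transcripts at 1 RPKM or more and at least 4-fold above all 3 other libraries, against 8 and 1 in the controls and 2 in nicotinic acid replicate 1. Downward it did not stand apart at the 4-fold cut. There, 6 transcripts lay below all 3 others, against 3 and 15 in control replicates 1 and 2 and 3 in nicotinic acid replicate 1. By smaller amounts its abundant transcripts did lie lower. Among the 514 with a mean over 100 RPKM, its median log2 difference from the mean of the other 3 libraries was -0.39. In the other libraries that median was 0.09 to 0.11. In 64 of the 232 the gap was at least 10-fold. These 232 transcripts took 1.17% of its reads (95% interval 1.16 to 1.17), and 0.141%, 0.138% and 0.159% of the reads of control replicates 1 and 2 and nicotinic acid replicate 1. The most abundant of them had 21476 reads there and between 3085 and 4454 elsewhere. This library also listed the most transcripts, 15804 against 15158 to 15263, from the fewest reads.

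Across the 12025 tested transcripts, the median size of the log2 difference was 0.23 between the 2 controls and 0.36 between the 2 nicotinic acid libraries. Nicotinic acid replicate 1 differed from control replicates 1 and 2 by 0.20 and 0.24, close to the difference between the controls. Nicotinic acid replicate 2 differed from them by 0.39 and 0.41. Its levels relative to the mean of the other 3 libraries ran from a median of 0.23 (log2) in the least abundant 20% of transcripts to -0.19 in the most abundant 20%. In the other libraries these medians ran from -0.07 to 0.08. With this library left out, edgeR called 13 transcripts (11 higher, 2 lower), and with nicotinic acid replicate 1 left out it called 890 (642 higher, 248 lower); in each case the remaining nicotinic acid library was assumed to vary like the controls. All 6 transcripts of the full comparison were among both sets.

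**Figure D3:**
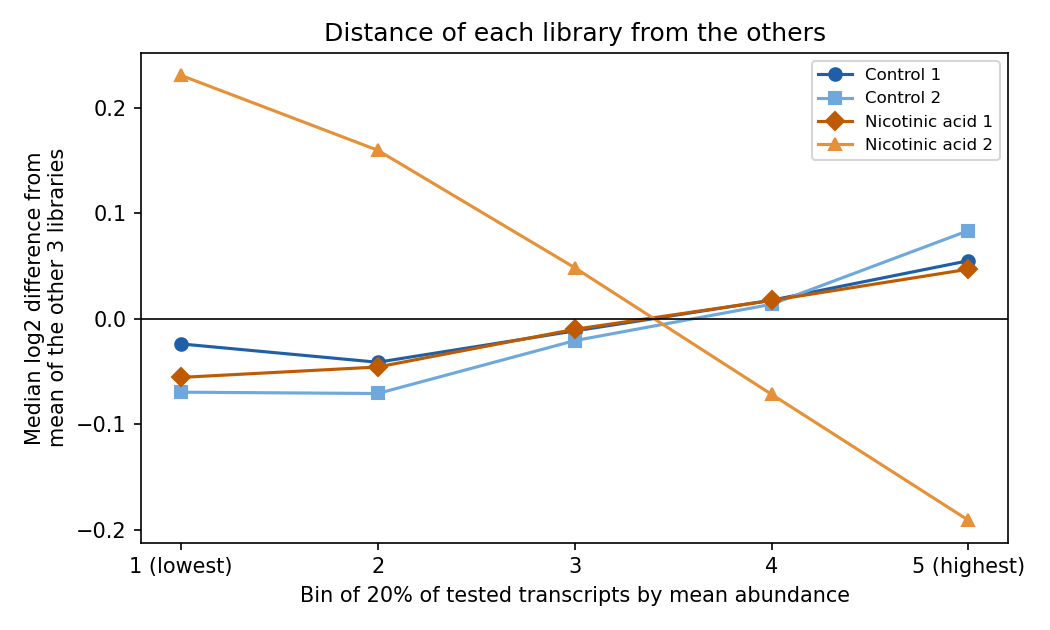
Median log2 difference of each library from the mean of the other 3 libraries, by bins of 20% of the tested transcripts ranked by mean abundance. Nicotinic acid replicate 2 falls from 0.23 in the lowest bin to -0.19 in the highest, while the other libraries stay between -0.07 and 0.08.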

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

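The count of 6 transcripts past the threshold stayed within 1.5 times (4 to 7) with RLE size factors, library totals alone, a mean RPKM of at least 5, a robust spread and a test against a log2 fold change of 1. It was 92 with no filter on low values, where 17158 transcripts were tested, and 60 in DESeq2 (50 higher, 10 lower). All 6 were among the calls of both. It was 3 in limma on log2(RPKM + 1) and 3 on log2(RPKM + 0.1), all 3 among the 6. Leaving out 1 library gave from 9 to 890 calls: 15 without control replicate 1, 9 without control replicate 2, 890 without nicotinic acid replicate 1 and 13 without nicotinic acid replicate 2. All 6 were among them except without control replicate 2, where 5 were; the lone library of the reduced group was assumed to vary like the other group. With the replicate block the count was 6, the same 6 transcripts, and no call was changed. The cause of the other changes was not tested. No named transcript reversed under any of the 14 alternatives. ENSBTAT00000006074 and ENSBTAT00000048100 stayed past the threshold in all 14, with adjusted p up to 0.042 and 0.047. ENSBTAT00000026725 missed it in 3 (adjusted p up to 0.096), and ENSBTAT00000001120, which missed it in the main test, passed in 8. Over all 14 the adjusted p of ENSBTAT00000001120 ran from 2.1e-13 (DESeq2) to 0.17 (edgeR against a log2 fold change of 1). With 2 libraries per group, edgeR called 40 percent of simulated 2-fold changes and 96 percent of 4-fold changes. Their spreads were drawn from the trend with abundance, and low-count transcripts were not among those changed. These shares may therefore be higher than in the real counts. Of the transcripts with both libraries of each group at least 4-fold apart, 14 tested ones did not pass. Such gaps, in tested transcripts or not, occurred in 22 transcripts in the real split and in 2 and 8 in the other splits. The other splits count any group difference as spread within pairs and are no baseline. Whether these 14 are missed changes therefore cannot be told. Set tests on the fixed gene lists were not run, and quantile normalization was planned for tables without counts.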

Other observations

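The tests of length bias, added RNA and regrouping below were chosen after the result was seen. Those of the most abundant transcripts, of a shared response and of read coverage were fixed before their result was seen.

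Transcripts listed in a single group were more frequent with nicotinic acid: 251 had a read in both nicotinic acid libraries and none in either control, against 117 in both controls and in neither nicotinic acid library. With at least 10 reads in each library of the group, the numbers were 2 and 0. Listed in 1 library alone were 521 transcripts of nicotinic acid replicate 2, and 308, 337 and 246 of control replicates 1 and 2 and nicotinic acid replicate 1. In all, nicotinic acid replicate 2 listed 15804 transcripts, and nicotinic acid replicate 1 listed 15231, between the controls (15263 and 15158). The 251 therefore cannot be told apart from the wider listing of replicate 2.

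Nicotinic acid replicate 2 stood apart from the other 3 libraries. Abundant transcripts taking the counts were examined for the 10 most abundant only, and those beyond them were not removed. These 10 are argued against as the whole cause. Without them, and with all libraries thinned to the same total, it still listed 489 transcripts more than the highest of the others, whose range was 67. The same held for a trend with transcript length, after whose removal its median distance from the others was 0.38 (log2) against at most 0.25. RNA of another cell type or tissue in that library stays open. Added RNA would lower by 1 factor the transcripts that it lacks, and would lower by less, or raise, those that it holds. Among the 514 transcripts over 100 RPKM the lower tail of that library's differences, from the 10th to the 1st percentile, was 0.39 (log2). This was shorter than the 0.66 to 0.98 of the others, although its median lay farther above its 10th percentile (0.43 against at most 0.36). From the median to the matching upper percentile it spanned 0.78, against 0.26 to 0.33 in the others. Each library was set against the mean of the other 3, so transcripts high in nicotinic acid replicate 2 lengthen the others' lower tails. The shorter tail therefore cannot decide. Without gene names the source could not be examined. A stronger response to nicotinic acid in that library also stays open. Its differences from 1 control correlated across transcripts with those of nicotinic acid replicate 1 from the other control at 0.142 and 0.137 (Pearson) in the 2 ways of dealing out the controls. By rank (Spearman) these were 0.111 and 0.095, so 1 of the 4 values lay under the bar of 0.1, which was set beforehand without naming the kind of correlation, and this test cannot tell. Within bins of 20% by abundance the Pearson values ran from 0.096 to 0.22, and 53.4% and 53.2% of transcripts had the same sign in both differences. How much of its distance such a response would cover was not measured, since the noise of single libraries lowers a correlation.

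The 6 transcripts past the threshold were weighed in the same way. For reads piled on part of a transcript, covered shares of bases were ranked among 100 transcripts of like read density and length per library. The median percentile was 58 (17 to 85.5 over the 6), so as a set they were not covered less than like transcripts. ENSBTAT00000006074 ranked lower, at 12 and 22 in nicotinic acid replicates 1 and 2, and the transcript of 2354 bases at 19 and 18. With 90.1% and 94.5% of the bases of ENSBTAT00000006074 covered, uneven depth over covered bases would not show, so piling stays open. With RLE size factors all 6 passed, and with library totals 5 did, at edgeR adjusted p up to 0.043. The 1 that missed the threshold had 0.083, with a log2 fold change of 5.15 against 4.95 with TMM. Of the 3 ways of dividing the 4 libraries into pairs, 1, the real one, gave as many as 6 transcripts and the highest other gave 0, but 3 splits are too few for a share under 0.05. A difference between the animals in the 2 groups that has nothing to do with the treatment was not tested, and a biological reading of these 6 is a hypothesis only.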
